A study of Homo sapiens with 16 samples.

How the data were processed

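The series holds 16 samples from the A375 melanoma line: 10 immunoprecipitated libraries with a peak list each (SMAD2/3, H3K27ac, MITF, ATF3 and JUNB, in vehicle and with TGFB1) and 6 inputs, which were not analysed here. Per the labels, cells were starved for 2 h and then given 10 ng/mL TGFB1 or the vehicle (4 mM HCl with 1 mg/mL BSA) for 2 h, chromatin was sheared to 200 to 300 bp, and 10 µg of antibody was used. The samples fell on 3 experiment dates. SMAD2/3 and H3K27ac shared 1 of them, MITF had its own, and ATF3 and JUNB shared the last, so antibody and date are confounded between most antibodies while each vehicle and TGFB1 pair shared its date. The design text speaks of technical triplicates, but the labels list 1 library for each antibody and treatment. No comparison therefore had replicates, and no p-value was computed.

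Per the labels, the authors aligned reads with Bowtie to GRCh38 and called peaks per library with MACS2 (version 2.0 stated). The fold enrichment ratio of each peak is the deposited value of the caller, pileup at the summit over the local background. The -log10 p and -log10 q values at each summit are those of the caller, as deposited by the authors. The deposited score is the whole part of the -log10 q multiplied by 10, as the caller writes it, and was not used. The lowest -log10 q in every list was near that of a q threshold of 0.05. Which input served as control, and how duplicates were handled, is not stated in the sources used here. Values of single peaks were used only to rank, filter or describe peaks within their own list.

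Peaks were compared with bedtools 2.31.1 and with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and drawn with matplotlib 3.10.9. Identical intervals listed for several summits were counted once. Peaks overlapped when they shared at least 1 bp, and a TGFB1-only or vehicle-only peak overlapped none of the other treatment for the same antibody. Shares carry 95% Wilson intervals. The level expected without a relation is the mean of 100 seeded random placements of the same peaks, for the transcription factors also within H3K27ac peaks of the TGFB1 library. Gene-free stretches are the longest stretch of each chromosome without an annotated gene, and sequence off chromosomes 1 to 22 and X was treated with them. This definition, the division of H3K27ac peaks by -log10 p at 5, 10 and 20, the division of SMAD2/3 peaks by strength, and the sets of 100 strongest peaks outside gene-free stretches were chosen after the lists had been examined.

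Depth was recovered from the lists. Fold enrichment and -log10 p were solved together for the pileup and background of each peak, assuming 1 pseudocount in each, and the pileup was a whole number within 0.01 reads for 99.98% of peaks or more in every list. Library size was then implied from the lowest background, the shortest peak as the read extension, and an assumed genome of 2.7 Gb. These sizes are estimates, and the extension differed within the SMAD2/3 pair (shortest peaks of 311 and 183 bp). The expected number of peaks still callable at the partner's depth was computed by binomial thinning of the recovered pileups. Applied to H3K27ac, thinning expected 80185 of the 80990 TGFB1 peaks to be callable at vehicle depth, while 63340 were shared. Thinning may thus overstate how far 2 libraries agree, but this pair also differed in treatment, which cannot be told apart.

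Genes were the 19974 protein-coding genes of the RefSeq table. Before the data were examined, 10 gene lists were fixed. A gene was counted when a summit lay in its body or within 10 kb, and each count was set beside 10000 seeded random lists matched on gene length (10 strata) and on a vehicle H3K27ac peak within 1 kb of a gene end. Named genes followed a fixed rule: for each antibody the 8 TGFB1-only, 4 vehicle-only and 4 shared peaks of highest -log10 p, each with the gene holding the summit or the nearest within 100 kb; up to 4 members of each gene list with a TGFB1-only SMAD2/3 peak; and the 8 TGF-beta targets with the strongest SMAD2/3 peaks. Peaks with no gene that near, or off the main chromosomes, were passed over. Some genes that the rule names are not reported here. The gene table used has no strand, so both gene ends stood in for the transcription start, and the planned search for AP-1 motifs was not run, since no genome sequence was used here. Alternatives were a -log10 q of at least 5, a fold enrichment of at least 6, reciprocal overlap of 50%, a 500 bp margin, equal list lengths, the top 5000 peaks of the partner list, summit inside the partner peak, other gene windows, and the removal of gene-free stretches.

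Overlaps, recovered pileups, thinning and gene list counts were tested on simulated data, while the random placements and the implied library sizes were not. All planted overlaps among 5000 simulated peaks were found, and none was called among peaks placed apart. Of 19302 simulated pileups, 99.99% were recovered. Thinning expected 83.0% of 2977 simulated peaks to be callable, and 83.1% were. Of 300 unrelated gene lists 3.67% passed the 95th percentile, and 77.0% did when enriched 3 times. These simulated lists were matched on gene length alone. Fewer simulated genes held a peak than in the SMAD2/3, ATF3 and JUNB lists with TGFB1, so these rates need not carry over to them.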

Results

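Chromatin immunoprecipitation followed by sequencing was performed in A375, an established human melanoma cell line. Serum-starved cells received TGFB1, the ligand of the TGF-beta receptors, at 10 ng/mL for 2 h, or the vehicle for the same time. The antibodies recognised SMAD2/3 (the receptor-activated transcription factors of the pathway), H3K27ac (the acetylated histone mark of active promoters and enhancers), MITF (the master regulator of the pigment cell lineage), and ATF3 and JUNB (transcription factors of the AP-1 superfamily). Each of the 10 combinations of antibody and treatment had 1 library with a peak list, so no difference below has a replicate check. The intervals are 95% Wilson intervals over peaks and cover counting error only. The depths implied by the peak values were 9.37 and 10.2 M reads for SMAD2/3 (vehicle, then TGFB1), 21.5 and 23.2 M for H3K27ac, 7.38 and 7.40 M for MITF, 6.38 and 28.1 M for ATF3, and 34.1 and 47.7 M for JUNB. Fold enrichments and -log10 p values of single peaks are the authors' own, and sites named below as strongest are those of highest -log10 p with a protein-coding gene within 100 kb.

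**Figure D1:**
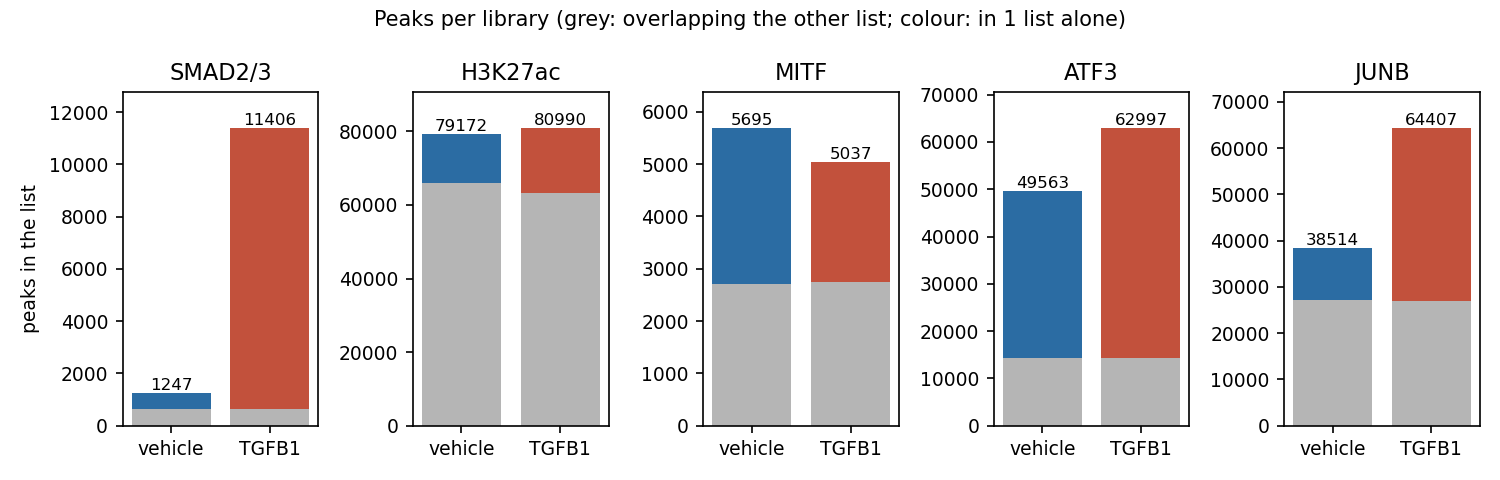
Number of peaks in each library, with 1 panel per antibody, its own vertical axis, and 1 library per bar. Grey is the part that overlaps a peak of the other treatment and colour the part in 1 list alone. The SMAD2/3 list grows from 1247 to 11406 peaks, and the MITF list is the shorter one with TGFB1 (5037 against 5695).

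The first comparison asked where SMAD2/3 lay on chromatin with and without the ligand. SMAD2/3 was called at 11406 sites after TGFB1 and at 1247 sites in vehicle, a ratio of 9.15. Of the TGFB1 sites, 10761 overlapped no vehicle peak, and 5.65% (5.25 to 6.09%) did, where random placement of the same peaks gave a mean of 0.038%. The short vehicle list limits this share. In the other direction, 50.1% (47.3 to 52.9%) of the vehicle peaks overlapped a TGFB1 peak. The vehicle list lay mostly in sequence without genes: 784 of its peaks (62.9%, 60.2 to 65.5%) lay in the longest gene-free stretch of a chromosome or on an unplaced contig, against 4.20% (3.85 to 4.58%) of the TGFB1 list. Outside those regions the numbers were 463 and 10927, a ratio of 23.6. In the TGFB1 list, 19.5% (18.8 to 20.3%) of summits lay within 1 kb of an end of a protein-coding gene, 36.5% lay elsewhere in gene bodies and 44.0% lay outside genes.

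Among SMAD2/3 peaks found with TGFB1 alone and with a protein-coding gene within 100 kb, the highest -log10 p (228, fold enrichment 51.2) was on chromosome 3 from 194133880 to 194135346, 1.08 kb outside HES1, a Notch-responsive repressor (GRCh38 throughout). It was followed by peaks outside ARHGAP27 on chromosome 17 (45371604 to 45372098) and outside STX16 on chromosome 20 (58623714 to 58624245). BHLHE40, a transcriptional repressor, had its peak on chromosome 3 from 4986664 to 4987265, 1.67 kb outside the gene, with a fold enrichment of 34.6. The next were 66.8 kb outside LOC102724877, inside MYH16 and 5.52 kb outside PLXND1 (a semaphorin receptor). These 7 sites all lay on H3K27ac called in both treatments and on a JUNB peak of the TGFB1 library. Among sites called in both lists, the highest were inside CFAP99 (chromosome 4, 2429971 to 2430716, fold enrichment 89.2), outside LEKR1, outside DNAH17 and inside CD44, the hyaluronan receptor (chromosome 11, 35166542 to 35167188). The vehicle-only sites named by the same rule were near ROCK1, AGBL4, TRIM16 and CNTNAP2, after 245 stronger ones without a gene that near had been passed over by the last. These 4 carried no H3K27ac and the ROCK1 site lay in a gene-free stretch, but 39 of the 99 vehicle-only sites outside such stretches overlapped vehicle H3K27ac.

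Known TGF-beta target genes stood far apart from matched random genes. Of the 35 genes in that list, 29 had a SMAD2/3 peak in the gene or within 10 kb with TGFB1, against a median of 11 in random lists matched on gene length and promoter acetylation; none of 10000 random lists reached 29. In vehicle 8 of the 35 had one, against a random median of 1, and none of 10000 lists reached 8. These genes thus stood apart without added ligand as well, but so did housekeeping genes (4 of 18, reached by 4 lists). The targets of highest -log10 p with TGFB1 included COL7A1 (type VII collagen), BHLHE40 and LTBP2 (a matrix protein of the latent TGF-beta binding family). SKIL (a SMAD co-repressor), TGFBI, JUNB and SKI were also among them. The COL7A1 peak, 0.359 kb outside the gene on chromosome 3 (48595490 to 48596180), had a fold enrichment of 31.2 and was shared with vehicle, as was the SKIL peak. SMAD7, the inhibitory SMAD, which was chosen here after its values were seen, had 9 peaks with TGFB1 and 1 in vehicle.

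The AP-1 family and matrix genes were also covered more often than matched lists. SMAD2/3 peaks lay at 10 of 15 AP-1 family genes (random median 4, reached by 13 of 10000 lists), led among TGFB1-only peaks by JUNB, FOSL1, JUND and ATF3. Extracellular matrix and mesenchymal genes had them at 13 of 22 (median 7, reached by 37 lists), led by the gelatinase gene MMP2, VIM (vimentin), COL4A2 and COL1A1. COL4A1 was counted through 1 peak alone, whose summit lay inside the adjoining COL4A2. Pigment cell genes had SMAD2/3 peaks at 12 of 22 (median 7, reached by 225 lists), with PMEL and CDK2 counted through the same peak. The pigment cell list was led by MET, GPNMB, OCA2 and MITF itself, whose peak lay inside the gene on chromosome 3 from 69775890 to 69776147. Neural crest and dedifferentiated melanoma genes had them at 9 of 17 (reached by 767 lists), with TGFB1-only peaks at NES, EGFR and TWIST2 and a shared peak of -log10 p 229 inside AXL, and lysosome genes at 8 of 20 (3221 lists), with SQSTM1, CTSA, PSAP and CTSD. Housekeeping genes had them at 9 of 18 (492 lists), with GAPDH, TUBB and RPLP0, and 4 of these 18 genes had a peak in vehicle, which only 4 of 10000 random lists reached. Cytokine and NF-kappaB genes were near the random median of 5, at 5 of 20, with NFKBIA, NFKB1, CXCL2 and LIF. Genes of other cell types had them at 5 of 18 (1827 lists), with PTPRC, NEUROD1, PECAM1 and GFAP. Interferon and antigen presentation genes were on the low side, at 4 of 26 (median 7; 918 lists had 4 or fewer), with weak peaks near ISG15, IFIT1, NLRC5 and MX1.

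**Figure D2:**
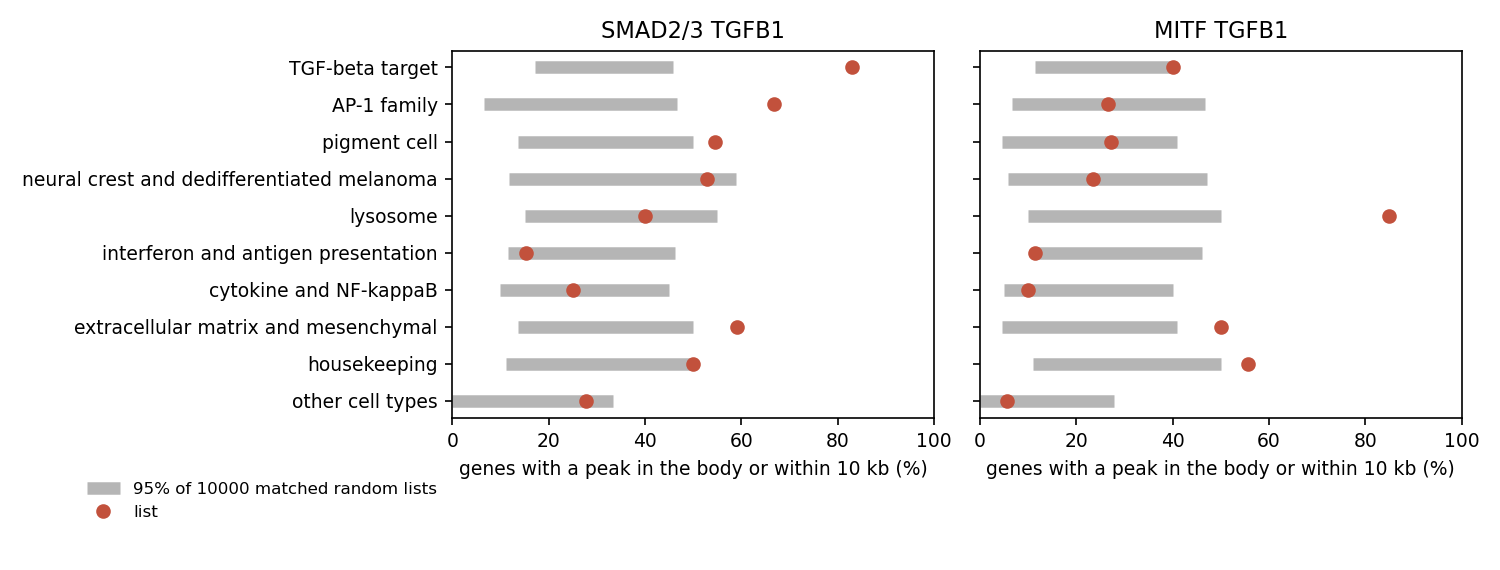
Percent of the genes of each fixed list with a peak summit in the gene body or within 10 kb, for the SMAD2/3 (left) and MITF (right) libraries with TGFB1. Red points are the lists and grey bars hold 95% of 10000 random lists matched on gene length and promoter acetylation. TGF-beta target genes stand apart in the SMAD2/3 panel (29 of 35) and lysosome genes in the MITF panel (17 of 20).

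H3K27ac was nearly the same in extent under both treatments, but most of the strongest peaks called with TGFB1 alone lay at SMAD2/3 sites. The lists held 79172 peaks in vehicle and 80990 with TGFB1, a ratio of 1.02, and 78.2% (77.9 to 78.5%) of the TGFB1 peaks overlapped a vehicle peak. Of the 17650 peaks called with TGFB1 alone, 3.13% overlapped a SMAD2/3 peak of TGFB1-treated cells (0.26% under random placement), compared with 0.48% of the 13319 vehicle-only peaks (0.25% under random placement) and 12.9% of shared peaks. The split widened with strength: among peaks with a -log10 p of at least 20, 147 of 438 TGFB1-only peaks (33.6%, 29.3 to 38.1%) held SMAD2/3, and 0 of 35 vehicle-only peaks did (0 to 9.89%). That class was not matched in strength, since its TGFB1-only peaks reached 127 and its vehicle-only peaks 33.1. In the class from 10 to 20 the shares were 6.54% of 2997 TGFB1-only and 0.493% of 1419 vehicle-only peaks. Of the 100 TGFB1-only peaks of highest -log10 p outside gene-free stretches, 62 held SMAD2/3, and of the 100 such vehicle-only peaks none did, while 76 of the 100 strongest shared peaks did. These sets differ in strength, with -log10 p from 33.4 to 127 for TGFB1-only, 17.1 to 33.1 for vehicle-only and 333 to 420 for shared peaks.

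The 8 strongest acetylation peaks seen with TGFB1 alone all overlapped SMAD2/3 called with TGFB1. They lay 91.1 kb outside LOC124906252, outside TNFRSF13B, inside YEATS4, 34.1 kb outside TGFBI, 26.5 kb outside FZD2 (a Wnt receptor), inside DHRS3 (a retinal reductase), inside SLC2A12 (a glucose transporter) and 61.6 kb outside PMEPA1, a feedback inhibitor of TGF-beta signalling. The TGFBI peak covered chromosome 5 from 135994251 to 135995657 with a fold enrichment of 22.9, and the PMEPA1 peak chromosome 20 from 57772881 to 57774821 with 14.4. Strong vehicle-only peaks near KCTD3, MBNL2 and COL6A2 held no SMAD2/3. The strongest shared peaks were at HNRNPR, BANP, OTUD4 and AHRR. By gene list, TGFB1-only acetylation lay at 23 of 35 TGF-beta target genes (median 11 in matched random lists, reached by 0 of 10000) and at 16 of 22 matrix and mesenchymal genes (median 8, reached by 2), while vehicle-only acetylation lay at 13 and 10 of them, with medians of 11 and 7.

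**Figure D3:**
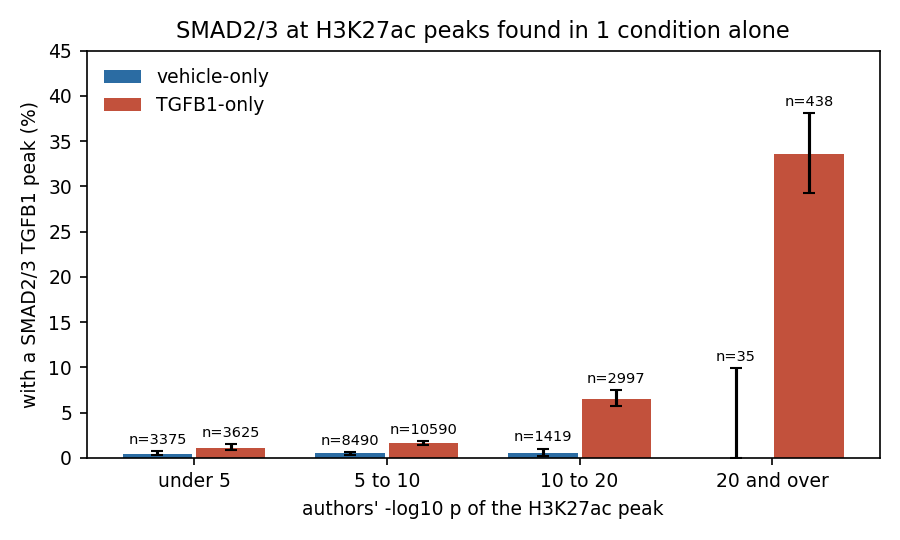
Percent of H3K27ac peaks found in 1 treatment alone that overlap a SMAD2/3 peak of the TGFB1 library, by the authors' -log10 p of the H3K27ac peak. Bars are shares with 95% Wilson intervals and n is the number of peaks; at 20 and over the shares are 33.6% of 438 TGFB1-only peaks and 0 of 35 vehicle-only peaks.

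The next comparison asked which other factors occupied the SMAD2/3 sites. Most SMAD2/3 sites of TGFB1-treated cells lay on chromatin that was acetylated without the ligand: 69.5% (68.6 to 70.3%) overlapped a vehicle H3K27ac peak and 75.7% (74.9 to 76.4%) one from TGFB1-treated cells, with 3.07% and 3.26% under random placement. JUNB was the most frequent factor, at 62.0% (61.2 to 62.9%) with TGFB1 and 48.0% in vehicle. ATF3 was at 45.9% and 18.6%, and MITF at 11.9% (11.3 to 12.5%) and 13.0%. For SMAD2/3 peaks outside gene-free stretches the MITF shares were 11.6% with TGFB1 and 11.2% in vehicle, so its higher vehicle share was not kept. The order of JUNB, ATF3 and MITF follows the list lengths of 64407, 62997 and 5037 peaks with TGFB1. For the top 5000 peaks of each the shares were 19.99% for JUNB, 11.8% for MITF and 7.78% for ATF3. ATF3 and JUNB were both present at 42.3% of the sites, and 9.68% overlapped none of the 4 other marks. The ATF3 values cannot be set against each other at equal depth, since the vehicle library was the shallower by a ratio of 4.41.

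The shared occupancy was above that of uniform placement within acetylated chromatin. For the 6217 SMAD2/3 peaks centred in an H3K27ac peak, JUNB was present at 59.3% (58.1 to 60.5%), against 20.2% when the same peaks were placed at random within H3K27ac peaks. The values were 41.1% against 14.0% for ATF3 and 12.8% against 2.96% for MITF. Every base of the H3K27ac peaks was equally likely in this placement, so a common preference for certain parts of them was not excluded. JUNB, ATF3 and MITF were all more frequent at stronger SMAD2/3 sites. Among the 2852 peaks of lowest -log10 p they were at 46.6%, 31.1% and 7.71%, and among the 2852 of highest -log10 p at 79.5%, 66.7% and 19.1%, while H3K27ac was at 77.5% and 78.3%. Stronger peaks may also be wider, which by itself would add overlaps.

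**Figure D4:**
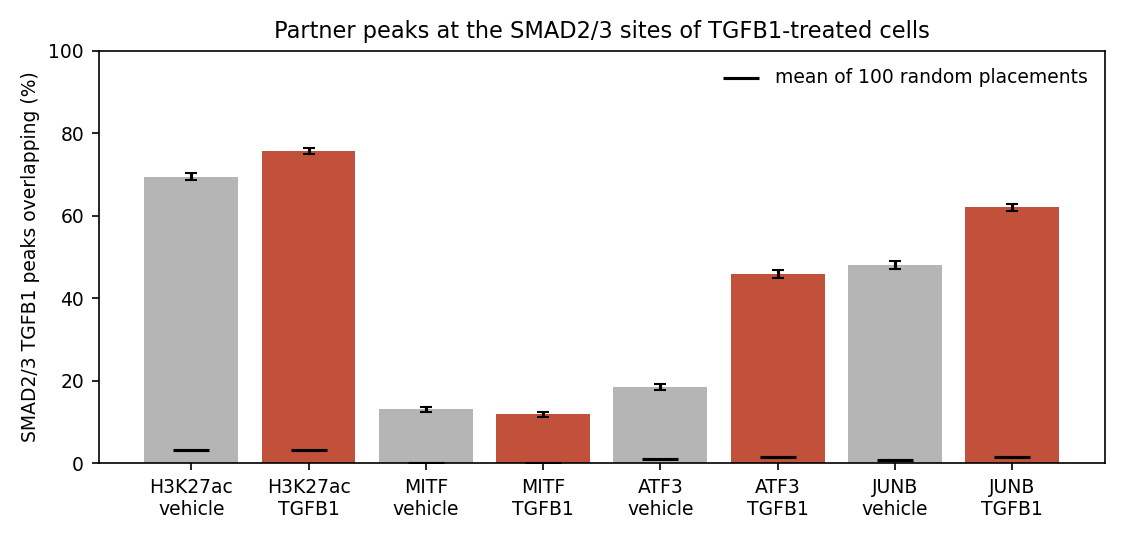
Percent of the 11406 SMAD2/3 peaks of TGFB1-treated cells that overlap a peak of each other library by at least 1 bp, with 95% Wilson intervals; grey is vehicle, red is TGFB1. Black dashes are the means of 100 random placements, none above 3.26%. H3K27ac and JUNB with TGFB1 are highest, at 75.7% and 62.0%.

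JUNB was called at more sites with the ligand, and its TGFB1-only sites held the other factors less often than its shared ones, which were also the stronger peaks (median fold enrichment 8.68 against 4.36). The lists held 38514 peaks in vehicle and 64407 with TGFB1, a ratio of 1.67, and 70.8% (70.3 to 71.2%) of vehicle peaks overlapped a TGFB1 peak. Shared JUNB sites overlapped ATF3 of the TGFB1 library at 59.98% and SMAD2/3 at 19.6%; the 37457 TGFB1-only sites did so at 21.4% and 4.73%, and the 11262 vehicle-only sites at 7.92% and 1.86%. The strongest TGFB1-only sites were inside IGF1R (chromosome 15, 98889907 to 98890415, fold enrichment 20.2), inside TCF4 and MAMDC2, outside C13orf46, inside PRKCI and DOC2B, outside C12orf75 and inside PRR16. The sites in IGF1R and MAMDC2 and the one outside C13orf46 also held SMAD2/3. The strongest shared sites were outside ANKRD10 and PHC2, inside the receptor tyrosine kinase gene AXL (chromosome 19, 41225533 to 41226676) and outside LAMC1, a laminin chain; all 4 held SMAD2/3 and ATF3. The strongest vehicle-only sites were inside DUX4 (a gene repeated in tandem, where reads are hard to place) and NEK9, and outside FRG2B and DEFB124. TGFB1-only JUNB peaks lay at 30 of 35 TGF-beta targets (median 23 in matched lists, reached by 38 of 10000) and 19 of 22 matrix genes (median 15, reached by 186). The whole vehicle JUNB list also stood above matched lists at these genes. It lay at 29 of 35 TGF-beta targets (median 20, reached by 8) and 18 of 22 matrix genes (median 14, reached by 245).

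ATF3 was called at 49563 sites in vehicle and 62997 with TGFB1, a ratio of 1.27 overall and of 2.09 outside gene-free stretches and contigs. Of the TGFB1 sites 22.8% (22.4 to 23.1%) overlapped a vehicle peak. The strongest TGFB1-only ATF3 sites were inside FOXP1 (chromosome 3, 71510857 to 71511417, fold enrichment 40.4) and MGAT4C, outside PEG10, inside the malic enzyme gene ME1 and PDZD2, and outside ABI3BP, ELK3 and ASAP1. The sites near PEG10 and ELK3 also held SMAD2/3. The strongest shared sites were outside HNRNPA3 (fold enrichment 111.0), at GZF1, and outside KLHDC4 and GLRX2, and all 4 carried H3K27ac in both treatments. Those of the vehicle list alone lay 87.7 kb from CWH43, 36.3 kb from TUBB8 at the end of chromosome 10, 87.1 kb from TPTE, and inside SIPA1L1; only 3 of the 100 strongest outside gene-free stretches overlapped H3K27ac with TGFB1. TGFB1-only ATF3 peaks lay at 34 of 35 TGF-beta targets (median 22 in matched lists, reached by 0 of 10000) but also at 19 of 20 lysosome genes (median 14, reached by 67) and 16 of 18 housekeeping genes (median 11, reached by 61). Vehicle-only ATF3 peaks lay at 16 of 35 TGF-beta targets (median 10, reached by 257), and the whole vehicle list at 25 of 35 (median 17, reached by 32). The 4.41-fold difference in depth limits any reading of these numbers.

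MITF lay at most lysosome genes, and often at gene ends, in both treatments. The MITF lists held 5695 peaks in vehicle and 5037 with TGFB1, a ratio of 0.884, at nearly equal depth, and 54.4% (53.0 to 55.7%) of the TGFB1 peaks overlapped a vehicle peak. Summits lay within 1 kb of a gene end for 37.0% (35.8 to 38.3%) of vehicle and 36.8% (35.5 to 38.1%) of TGFB1 peaks. Of 20 lysosome genes, 18 had a MITF peak in vehicle and 17 with TGFB1, with a median of 6 in both sets of matched lists, and 0 of 10000 lists reached either count. Only 6 of 22 pigment cell genes had one in each treatment, near the random median of 5. The strongest shared sites were at the gene ends of TFPT (chromosome 19, 54114999 to 54115892, fold enrichment 64.1), VPS51, UCKL1 and ANGEL1.

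MITF sites of the treatments differed in the genes beside them. AP-1 family genes had a vehicle-list MITF peak at 9 of 15 (median 3, reached by 19 of 10000 random lists) and a TGFB1-list peak at 4 of 15 (median 3, reached by 4341). The vehicle-only peaks were at JUND, ATF3, FOSL1, ATF4, JUN, MAFG, JUNB and FOSL2. With TGFB1, MITF lay at 14 of 35 TGF-beta targets (reached by 301 lists; 10 in vehicle, 4408 lists) and 11 of 22 matrix genes (32 lists; 7 in vehicle, 2365 lists), with TGFB1-only peaks at SKI, PMEPA1, COL4A2 and COL1A1. Housekeeping genes showed the same direction, at 10 of 18 with TGFB1 (96 lists) and 7 in vehicle. COL1A1 had MITF beside it in vehicle as well, since the SMAD2/3 peak outside that gene overlapped a MITF peak of each treatment. The strongest TGFB1-only sites were inside VILL and FRMD3, outside KLHDC4, inside KLHL26, outside NENF and PLK3, and inside MYO16 and LOC124901446, and 4 of the 8 held SMAD2/3. The strongest vehicle-only sites, after 14 to 21 stronger ones had been passed over, were inside TMEM150B, ARHGAP19 and DYNC1LI1 and next to TUG1. TGFB1-only MITF sites overlapped JUNB of the TGFB1 library at 51.5% and ATF3 at 36.5%, and vehicle-only sites at 32.5% and 21.9%. Of the vehicle-only sites 14.4% lay in gene-free stretches or on contigs, against 0.739% of TGFB1-only ones. Among the 100 strongest TGFB1-only and vehicle-only sites outside those stretches, 61 and 29 overlapped JUNB of the vehicle library. For ATF3 of the vehicle library the numbers were 25 and 13. The members of the lists that differ were named after their values were seen, and with 1 library per treatment these differences were not tested.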

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

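The MITF list was the shorter one with TGFB1, with a ratio of 0.884, while the other 4 antibodies had longer lists with TGFB1. The difference between the antibodies was not tested, since each had 1 library per treatment, and outside gene-free stretches the MITF ratio was 0.9497. Of the tests below, the share of ATF3 vehicle-only peaks in gene-free stretches was chosen after its result was seen. The definition of those stretches, which every test that names them uses, was chosen after the lists had been examined.

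The SMAD2/3 list was longer with TGFB1 by a ratio of 9.15. At the depth and read extension of the vehicle library, 8129 of the 11406 TGFB1 peaks were expected to stay callable, far above the 1247 called, which argues against depth as the whole cause. Calls in gene-free stretches and on contigs made up 62.9% of the vehicle list and 4.20% of the TGFB1 list. Leaving them out therefore had to raise the ratio, which became 23.6. Such calls do not account for the longer TGFB1 list, but this has no bearing on depth. An antibody yield differing between the 2 libraries for a reason other than TGFB1 cannot be told apart from the ligand, because there is 1 vehicle library. Ligand-driven binding may account for the pattern and remains a hypothesis.

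The ATF3 lists shared few sites. At the vehicle depth 36220 of the TGFB1 peaks were expected to be callable, while 14344 overlapped a vehicle peak. The 4.41-fold lower depth may thus remove part of the missing peaks, and the thinning argues against it as the whole cause. In the other direction, 53.8% of the vehicle-only peaks lay in gene-free stretches or on contigs, against 1.03% of TGFB1-only peaks, as calls in background sequence would give for that part; why the vehicle library held so many was not tested. Loss of ATF3 from acetylated chromatin was predicted to put vehicle-only peaks there at least as often as shared ones. Outside those stretches, 8.92% (8.49 to 9.37%) of the 16287 vehicle-only peaks overlapped vehicle H3K27ac, compared with 30.9% (30.1 to 31.7%) of the 12834 shared ones. The shares argue against such loss as the source of most vehicle-only peaks, but cannot exclude it for those that overlapped. Over the whole vehicle list, shared peaks were also stronger (median fold enrichment 6.81 against 5.18), which the comparison did not match. The origin of these 16287 peaks stays open, and the ATF3 pair gives no safe estimate of what TGFB1 does to ATF3.

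The JUNB list was longer with TGFB1 by a ratio of 1.67. At the vehicle depth 59995 of the 64407 TGFB1 peaks were expected to be callable, against 38514 called. Outside gene-free stretches the ratio was 1.69. These values argue against depth and against those regions as the whole cause. The library sizes behind the thinning are estimates, so a part played by depth was not excluded. For H3K27ac too, thinning expected more peaks to be callable than were shared. A difference in enrichment between 2 single libraries was therefore not excluded and may contribute. JUNB binding that follows TGFB1 is a hypothesis that more libraries per treatment would test.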

How the results depend on the processing

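No ratio of peak numbers changed direction under a -log10 q of at least 5, a fold enrichment of at least 6 or the removal of gene-free stretches, and 11 of 15 stayed within 1.5 times. The others were SMAD2/3 at 16.2 (fold enrichment) and 23.6 (gene-free stretches), and ATF3 at 1.93 (-log10 q) and 2.09 (gene-free stretches). The 29 TGF-beta targets with a SMAD2/3 peak became 24 to 32 under 4 alternatives. The percent of TGFB1 peaks overlapping a vehicle peak left its interval in 21 of 25 cases, in the order SMAD2/3, H3K27ac, MITF, ATF3 and JUNB as follows. Reciprocal overlap of 50% gave 4.36, 61.3, 47.7, 15.4 and 33.8. Equal list lengths gave 16.6, 79.1, 51.98, 27.3 and 63.1, and a 500 bp margin 6.13, 86.1, 56.3, 24.95 and 45.1. A -log10 q of at least 5 gave 79.0, 58.9, 21.8 and 47.4 for H3K27ac, MITF, ATF3 and JUNB, and removal of gene-free stretches 3.39 for SMAD2/3 and 20.97 for ATF3. The percent of SMAD2/3 peaks with a partner left its interval in 12 of 16 cases. With the summit inside the partner peak it was 53.8 (H3K27ac), 8.995 (MITF), 39.8 (ATF3) and 56.3 (JUNB). With the top 5000 partner peaks it was 20.3 (H3K27ac), 7.78 (ATF3) and 19.99 (JUNB), as shorter partner lists require. At a -log10 q of at least 5 it was 73.3 (H3K27ac), 9.76 (MITF) and 64.3 (JUNB), and outside gene-free stretches 78.9 (H3K27ac) and 63.2 (JUNB). Stricter overlap lowers a share by construction; for the other shifts the cause was not tested. Of the other gene list counts and percents, 297 of 396 and 21 of 72 stayed the same by these measures. Of the 40 named TGFB1-only peaks, 3 had a vehicle peak within 500 bp, as did 5 of the 20 vehicle-only ones with a TGFB1 peak, and 18 of the 20 shared ones passed reciprocal overlap. The gene-free, 500 bp and gene-end alternatives were chosen after the data were examined. No paired analysis was possible because each antibody and treatment had 1 library. Leaving out a library, the AP-1 motif share with its alternatives, and a 5 kb window around the transcription start were not run. Depth limits the ATF3 pair most.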

Other observations

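Several genes held more than 1 acetylation peak called with TGFB1 alone. They were chosen after their values were seen, and peaks per gene were not set against gene length. NEDD9, a scaffold protein of cell migration, had 14 TGFB1-only H3K27ac peaks and 1 vehicle-only peak, COL4A2 had 9 and 1, the receptor gene MET 7 and 4, TNC (tenascin C) 6 and 1, and ITGA5 3 and 1. PMEPA1 had 9 TGFB1-only peaks, COL5A1 had 8 and ANGPTL4 had 3. The strongest TGFB1-only peak at COL5A1 covered chromosome 9 from 134670370 to 134671310 inside the gene. Lysosome genes had TGFB1-only acetylation at 12 of 20, with a median of 7 in matched random lists (reached by 195 of 10000), and vehicle-only acetylation at 5 of 20.

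JUNB and ATF3 sites called with TGFB1 alone met SMAD2/3 at a collagen gene. The strongest TGFB1-only JUNB peak among the matrix genes was outside COL1A1 (chromosome 17, 50178076 to 50178775), and TGFB1-only peaks of ATF3 (50178174 to 50178759) and SMAD2/3 (50178064 to 50178738) lay at the same place. JUNB was called in the TGFB1 library at all 22 matrix and mesenchymal genes (median 17, reached by 8 of 10000 lists) and at all 17 neural crest and dedifferentiated melanoma genes (median 14, reached by 173). In the vehicle library JUNB was already at 18 of the 22 (median 14, reached by 245) and 16 of the 17 (median 11, reached by 27). TYRP1, a pigment enzyme gene, carried the strongest TGFB1-only ATF3 peak among the pigment cell genes (chromosome 9, 12708609 to 12708880). COL1A1 and TYRP1 were chosen after their values were seen.

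MITF and SMAD2/3 met more often than chance placement gave. Of MITF peaks of the TGFB1 library, 26.4% overlapped SMAD2/3 of the same treatment, and for the 2652 centred in acetylated chromatin the share was 30.6% (28.9 to 32.4%), against 7.43% when placed at random within H3K27ac peaks. The share was 26.3% for TGFB1-only and 24.9% for vehicle-only MITF sites, and outside gene-free stretches 26.4% (24.7 to 28.3%) and 22.4% (20.8 to 24.0%). Of the 100 strongest of each outside those stretches, 35 and 20 held SMAD2/3.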
